A study of Rattus norvegicus with 6 samples.

How the data were processed

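Kidney RNA from 6 rats aged 21 weeks was measured on Agilent one-colour rat arrays, 3 from diabetic animals and 3 from animals given Bailing Capsule, a fermented Cordyceps preparation. Per the labels, total RNA was extracted from tissue and labelled with Cy3. The labels give no dose, sex or strain, do not say whether the treated animals were diabetic, and name no untreated, non-diabetic group among the samples analysed here. The samples are labelled as separate replicates, and nothing else in the labels says how they were collected, so p-values measure the spread between these samples.

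Per the file headers, the arrays were read on a G2505C scanner and extracted with Agilent Feature Extraction 11.0.1.1, which gave for each spot an intensity after background subtraction and detrending, with no scaling between arrays. The deposited table of processed values holds log2 intensities that were quantile normalized between arrays and not centred per gene, as read from the values: the column medians lay between 5.05 and 5.06, and each column correlated with its own array at 0.983 to 0.994. The steps the authors took to make that table are not given in the sources used here, and it was used as an alternative only.

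Each array held 42877 spots other than the 1377 control spots, for 30367 probes. Spots flagged as outliers, 597 to 1091 per array, were left out, and spots of the same probe were averaged. The processed signal was taken to log2 and the 75th percentile of each array was subtracted. No spot was saturated. Between 64.55% and 73.46% of probes were well above background on an array, and the median coefficient of variation among repeated spots was 3.65% to 5.86%. The number of arrays limits the precision. A probe counted as well above background on an array where at least 50% of its spots were. It was kept where this held on all 3 arrays of at least 1 group, and the brightest kept probe with values on most arrays of each group stood for a gene. The files carry no gene symbols. RefSeq accessions on the array were matched, without versions, to a RefSeq gene table of assembly GRCr8, which named 18005 probes and left 12362 unnamed here. The array annotation names the older build rn4, so no coordinates are given. In all 17892 features were tested, 10633 of them named and 7259 unnamed, and 536 lacked a value on at least 1 array.

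Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes), with Benjamini-Hochberg adjustment, and a gene was called at an adjusted p under 0.05. All differences are Bailing Capsule minus diabetic. For a probe not well above background on any array of a group, the fold is a lower bound: the brighter group's mean against the mean, over the dim group's arrays, of the higher of the lowest signal well above background and the probe's own signal. Of 38 gene lists fixed before the data were examined, 37 had the minimum of 5 tested members and were tested with camera at a preset correlation of 0.01, with an estimated correlation and with fry as alternatives. Counts of list members are given over all genes tested and adjusted over the list alone. The lists covered kidney cell types, other cell types, fibrosis, injury, inflammation, lipid and glucose metabolism, mitochondria, stress responses, cell cycle, hormones and the circadian clock. The genes named in the text were chosen by a rule fixed at the same time: the 10 largest rises and 10 largest falls among named genes that were called with non-overlapping groups, up to 5 members by p of each list past its test, up to 3 of another list described by its members, and 12 fixed genes. A set of liver markers and a split of collecting duct genes into principal and intercalated cell genes were written after the data were examined. Some genes that the rule names are not reported here. Names outside this rule are marked where they appear.

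The arrays came from 2 slides scanned on 1 day. Slide 1 held all 3 Bailing Capsule arrays and diabetic replicate 1, and slide 2 held diabetic replicates 2 and 3. Group and slide are therefore partly confounded, and values with slide as a block are given for the lists that passed and for called genes whose call did not hold under the block. Since slide 2 held no Bailing Capsule array, the blocked log2 fold change equals the one within slide 1, which rests on 1 diabetic array.

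The design had assumed a mean spot signal and a gene name column. The files used here hold a median spot signal, which entered the normexp alternative, with an offset of 50. Other alternatives were quantile and median scaling, the deposited log2 table, no filter or a filter on all 6 arrays, the mean of a gene's probes, each probe on its own, other variance models, array weights, blocks, a minimum fold of 1.2 and leaving out each array.

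The tests were tried on simulated arrays drawn from the means and spreads of 17356 features, with 3 arrays per group. Of genes changed by 1 log2 unit, 7.35% were recovered. At 2 log2 units 71.2% were recovered, and at 3 log2 units 84.8%, with 3 false calls. A simulated shift of 1 list was called and 0 other lists were. The genes were simulated as independent, so this does not show how often lists of correlated genes are called falsely.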

Results

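Gene expression was measured in the kidneys of 3 diabetic rats and 3 rats given Bailing Capsule, all 21 weeks old. The series asks how the preparation affects renal gene expression. Pairs of arrays correlated at 0.966 to 0.992 across genes, and the first principal component, with 42.3% of the variance, did not separate the groups.

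The largest falls in Bailing Capsule kidneys included Atp12a, Mogat2, Creb3l3, Mttp and Gpr83. Atp12a, the non-gastric proton-potassium pump, fell by 5.53 on the log2 scale (SE 0.38), and was well above background on 1 of the 3 Bailing Capsule arrays. Mogat2, which acylates monoacylglycerol in triglyceride synthesis, was 22.3-fold lower, from 1.61 ± 0.56 to -2.87 ± 0.57 (log2, SD, n = 3). Creb3l3, a membrane-bound transcription factor of lipid metabolism, was 11.7-fold lower, and Mttp, which loads lipid onto apolipoprotein B, was 9.16-fold lower. The G protein-coupled receptor gene Gpr83 was not well above background on any Bailing Capsule array and was at least 18.3-fold lower.

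The other large falls were in Cyp24a1, the vitamin D 24-hydroxylase (5.94-fold), Cldn14, a claudin of the thick ascending limb (6.18-fold), and Il1rl1, the interleukin-33 receptor (5.73-fold). Scrg1 and Calca, which encodes calcitonin and its related peptide, were not well above background on any Bailing Capsule array and were at least 4.2-fold and 2.92-fold lower. Adjusted p-values of these 10 genes ran from 9.19e-05 for Gpr83 to 0.0369 for Cldn14.

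The largest rise was in Prima1, which anchors acetylcholinesterase in the membrane, at 4.59 on the log2 scale (SE 0.30). A further probe of Prima1 gave -0.27, so its probes disagree. Anxa13, an epithelial annexin, was 11.8-fold higher, with 1 of 3 diabetic arrays well above background, the chloride channel gene Cftr 11.5-fold and the ligand gene Wnt2b 9.91-fold. Irf7, a regulator of type I interferon, was 7.99-fold higher (adjusted p = 0.0493). Shisa3 rose 5.04-fold and Rec114, well above background on 1 diabetic array, 4.92-fold. Wnt2b was well above background on 2 of the 3 diabetic arrays, and Mttp and Il1rl1 on 2 of the 3 Bailing Capsule arrays. The folds of these genes and of Atp12a are therefore imprecise. With normexp the log2 values were 1.15 for Anxa13, 0.57 for Rec114, 1.46 for Wnt2b, -0.96 for Mttp and -0.62 for Il1rl1, none of them called, and -2.58 for Atp12a, which was called. The olfactory receptor gene Or5m10, the cytochrome P450 gene Cyp3a9 and the glycoprotein hormone subunit gene Cga were not well above background on any diabetic array, and were at least 3.16-fold, 2.35-fold and 4.29-fold higher. Such bounds hold for the main processing only. Under the alternatives the log2 values smallest in size were 0.40 for Or5m10, 0.31 for Cyp3a9 and 0.45 for Cga. For Gpr83, Scrg1 and Calca they were -1.48, -0.54 and -0.34.

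**Figure D1:**
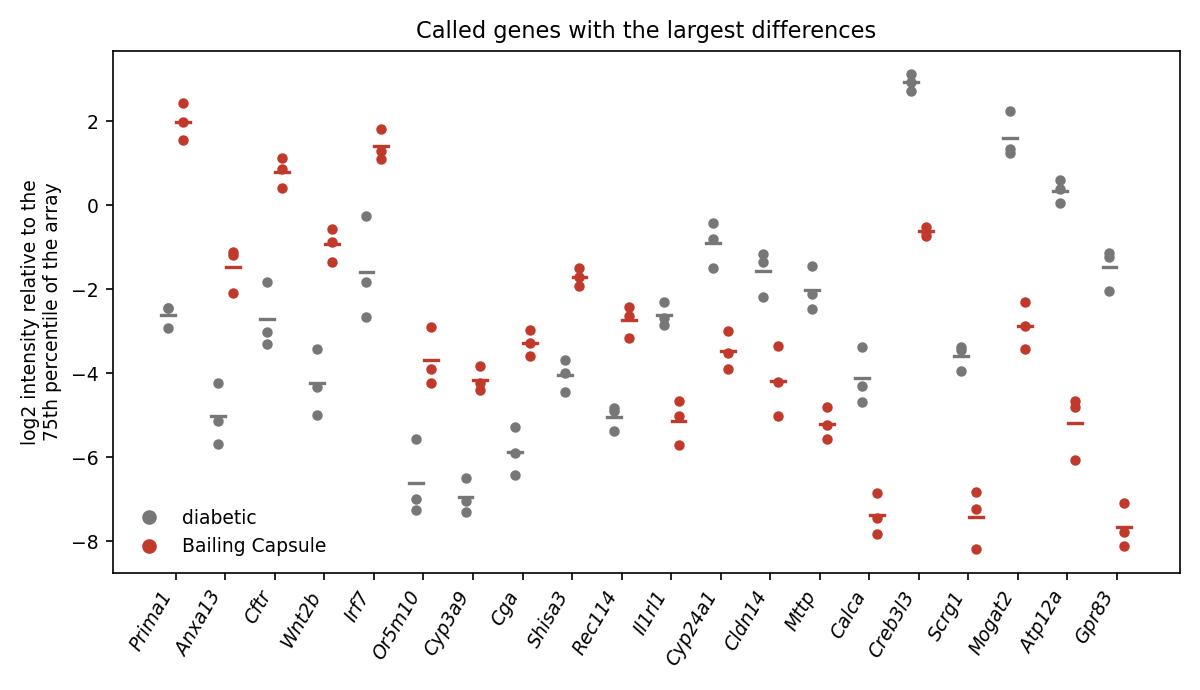
Log2 intensity relative to the 75th percentile of each array for the 20 named genes with the largest called differences; points are arrays, grey for diabetic and red for Bailing Capsule, and bars are group means of 3. The groups do not overlap for any of these genes. Signals that are not well above background in 1 group, such as those of Gpr83, give a lower bound of the gap.

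limma called 57 of 17892 features at an adjusted p under 0.05, 23 higher and 34 lower in Bailing Capsule kidneys, of which 18 and 27 have names. The share called higher was 40.4%, against 55.6% (25 higher and 20 lower) in the deposited quantile-normalized values. At an unadjusted p under 0.05 there were 1350 features, where independent tests with no difference would give 895. Other splits of the 6 arrays into 3 and 3 gave 87 to 3870, so 895 is not the level that regrouping these arrays gives. The split with 3870 set diabetic 1 and Bailing Capsule 2 and 3 against the rest, the same arrays that the first principal component parts. Groups did not overlap for 11.6% of features, where chance gives 10%.

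With slide as a block 38 features were called, 28 higher and 10 lower, of which 18 were among the 57, and within slide 1 there were 9. All 56 calls that had a value kept their sign under the block. No called feature had overlapping groups, so this sign was fixed in advance and says nothing about slide. Of the 20 named genes above, 14 passed with the block; Irf7, Or5m10, Shisa3, Rec114, Calca and Cldn14 did not. Of these, Shisa3 went from 2.33 to 2.28 under the block, Rec114 from 2.30 to 2.17 and Cldn14 from -2.63 to -2.01. Calca, with signals near background, went from -3.26 to -2.69. The blocked values of Irf7 and Or5m10 were smaller, at 1.67 from 3.0 and 1.89 from 2.92, the latter with diabetic signals near background. Diabetic replicate 1, on slide 1, differed from the other diabetic arrays at 1083 features, 3 of them shared with the 57 in direction; this sets 1 array against 2 and assumes that it varies as they do, so the count cannot be compared with the 57. The count was 195 without diabetic replicate 1, 17 without diabetic replicate 2 and 18 without diabetic replicate 3. It was 141, 28 and 33 without Bailing Capsule replicates 1, 2 and 3.

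Genes of fatty acid oxidation and targets of PPAR alpha, the nuclear receptor that drives it, were lower in Bailing Capsule kidneys. Of 29 tested members 28 had negative values, with a median log2 fold change of -0.70. Over all genes 4 members passed. Angptl4, an inhibitor of lipoprotein lipase, fell 4.13-fold, Vnn1, a pantetheinase, 3.4-fold, and Plin2, which coats lipid droplets, 3.20-fold. None of these 3 calls held with slide as a block, where the values were -2.19 (adjusted p = 0.0789), -1.90 (0.0751) and -1.76 (0.132). Adjusted over the list alone, 11 members were lower. Pdk4, which restrains pyruvate oxidation, had -2.75 (adjusted p = 0.129). The array medians, relative to the diabetic mean, were -0.72, -0.73 and -0.80 in Bailing Capsule kidneys against -0.09, 0.19 and -0.09 in diabetic kidneys. camera gave an adjusted p of 3.85e-15, adjusted p = 0.352 with an estimated correlation, and fry gave an adjusted p of 0.0229. The slide-blocked median was -0.67, which rests on 1 diabetic array. In the same comparison 10 tested liver marker genes had a median of -0.98.

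Genes induced by interferon were higher in Bailing Capsule kidneys, with a median of 0.78 over 20 tested members. Irf7 and Usp18, which removes the interferon-induced modifier ISG15, passed over all genes. A further probe of Usp18 was not well above background on any diabetic array. It was at least 2.21-fold higher and did not pass (adjusted p = 0.15 among single probes in limma). Neither call held with slide as a block: Irf7 had 1.67 (adjusted p = 0.277) in place of 3.0, and Usp18 1.67 (adjusted p = 0.171) in place of 2.22. Isg15 itself had 2.02 (adjusted p = 0.0971), the antiviral genes Mx1 1.34 and Oasl2 1.38. Adjusted over the list alone 11 members were higher and 1 lower, which was Dhx58 at -1.09, named after its value was seen. The array medians were 0.77, 0.72 and 0.78 against 0.22, 0.00070 and -0.35. camera gave an adjusted p of 4.84e-11, adjusted p = 0.407 with an estimated correlation, and fry did not call the list (adjusted p = 0.191). The slide-blocked median was 0.49.

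Markers of the collecting duct were higher, with a median of 0.43 over 17 members, and Slc26a4, the chloride-bicarbonate exchanger pendrin of intercalated cells, rose 3.21-fold (adjusted p = 0.0457). The call of Slc26a4 did not hold under the slide block, at 1.87 (adjusted p = 0.131) in place of 1.68. The other intercalated cell genes named by the rule, the proton pump subunits Atp6v1g3 and Atp6v0d2 and the exchanger Slc4a9, had 1.09, 0.74 and 0.83 and did not pass over all genes. The water channel gene Aqp3 of principal cells had -0.84. Adjusted over the list alone 2 members were higher and 1 lower. The array medians overlapped, at 0.45, 0.43 and 0.35 against -0.18, 0.37 and -0.17. camera gave an adjusted p of 0.000171, adjusted p = 0.507 with an estimated correlation, and with slide as a block the median was 0.63.

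Markers of red cells and blood were also higher. All 7 tested members had positive values, from 0.02 to 1.04, with a median of 0.69, and 0 passed over all genes. The values of Alas2, of haem synthesis, Pf4, of platelets, and Hbb-b1, a haemoglobin chain, were 1.04, 0.83 and 0.69, and Alas2 passed over the list alone. The array medians overlapped, at 0.82, 0.20 and 0.72 against -0.42, 0.08 and 0.40. camera gave an adjusted p of 0.000352, adjusted p = 0.507 with an estimated correlation. The median with slide as a block was 0.97.

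Genes of tubular injury were lower, with a median of -0.23 over 17 members. Clu, the chaperone clusterin, fell 2.93-fold (adjusted p = 0.0493), and 6 members were lower over the list alone. The call of Clu was lost under the slide block, at -1.59 (adjusted p = 0.217) in place of -1.55. The fibrinogen chain genes Fgb and Fga had -1.74 and -1.20, Spp1, which encodes osteopontin, -0.92, Gdf15 -1.09 and Lcn2 -0.91, none called over all genes. Havcr1, the injury marker KIM-1, had 0.05. Fibrinogen chains are also abundant in liver, and the 10 tested liver markers, 9 of them negative, had a median of -0.98. camera gave an adjusted p of 0.00286, adjusted p = 0.352 with an estimated correlation, and fry gave 0.0186. With slide as a block the median was -0.14, and without diabetic replicate 1 the camera call was lost (adjusted p = 0.0573).

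The remaining lists past camera's test held no called gene. Genes of p53 and apoptosis had a median of -0.35 with all 14 members negative (adjusted p = 0.0239), among them Zmat3 at -0.81 and Bbc3 at -0.74. Adipocyte markers had a median of -0.66 (adjusted p = 0.0469); Cidea and Adrb3 had -1.90 and -1.89 and passed over the list alone, and Lpl had 0.73. Their array medians were 0.16, -1.54 and -0.48 in Bailing Capsule kidneys, and without Bailing Capsule replicate 2 the adjusted p was 0.166. Circadian clock genes had a median of 0.17 (adjusted p = 0.0302), with Tef at 0.88 and Dbp at 0.96. With an estimated correlation the adjusted p-values of these lists were 0.507, 0.686 and 0.615. With slide as a block their medians were -0.24, -0.88 and 0.35. Without diabetic replicate 1 camera's adjusted p-values were 0.182, 0.465 and 0.0573.

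camera called 8 of 37 lists at the preset correlation, 0 with an estimated correlation (lowest adjusted p = 0.352) and fry called 2. Without diabetic replicate 1 there were 4 called lists, and without diabetic replicate 3 there were 14.

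**Figure D2:**
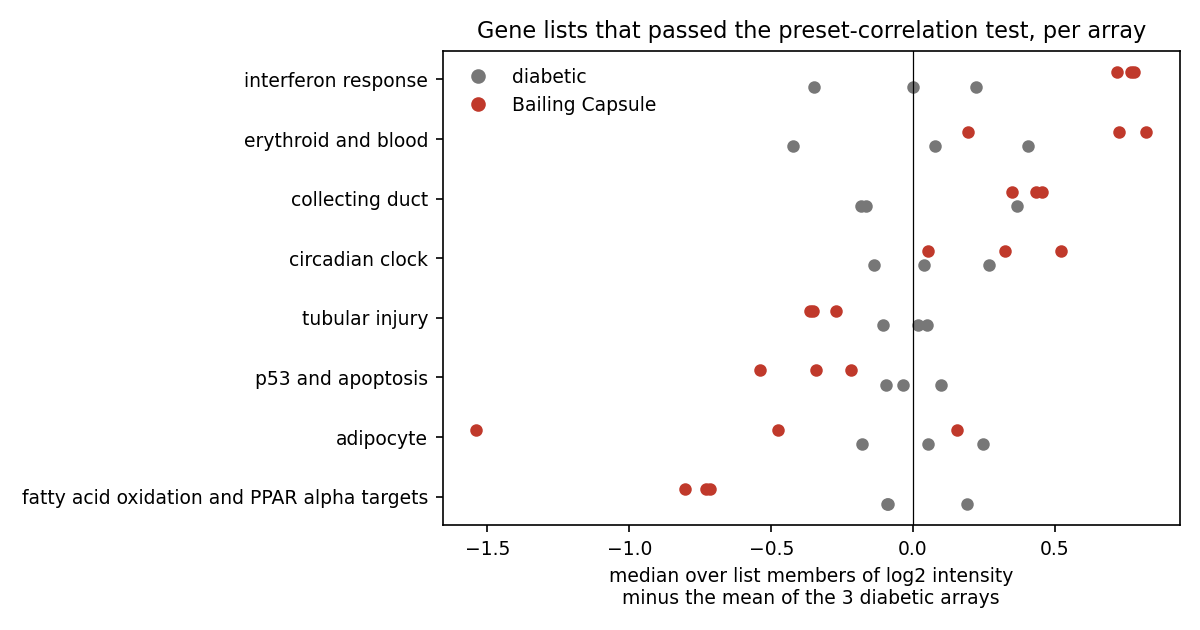
Median over list members of log2 intensity minus the mean of the 3 diabetic arrays, for the 8 lists past camera's test at the preset correlation; each point is an array, grey for diabetic and red for Bailing Capsule. The groups separate for fatty acid oxidation, -0.80 to -0.72 against -0.09 to 0.19, and for interferon, tubular injury and p53 genes. They overlap for collecting duct, blood, circadian clock and adipocyte genes.

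**Figure D3:**
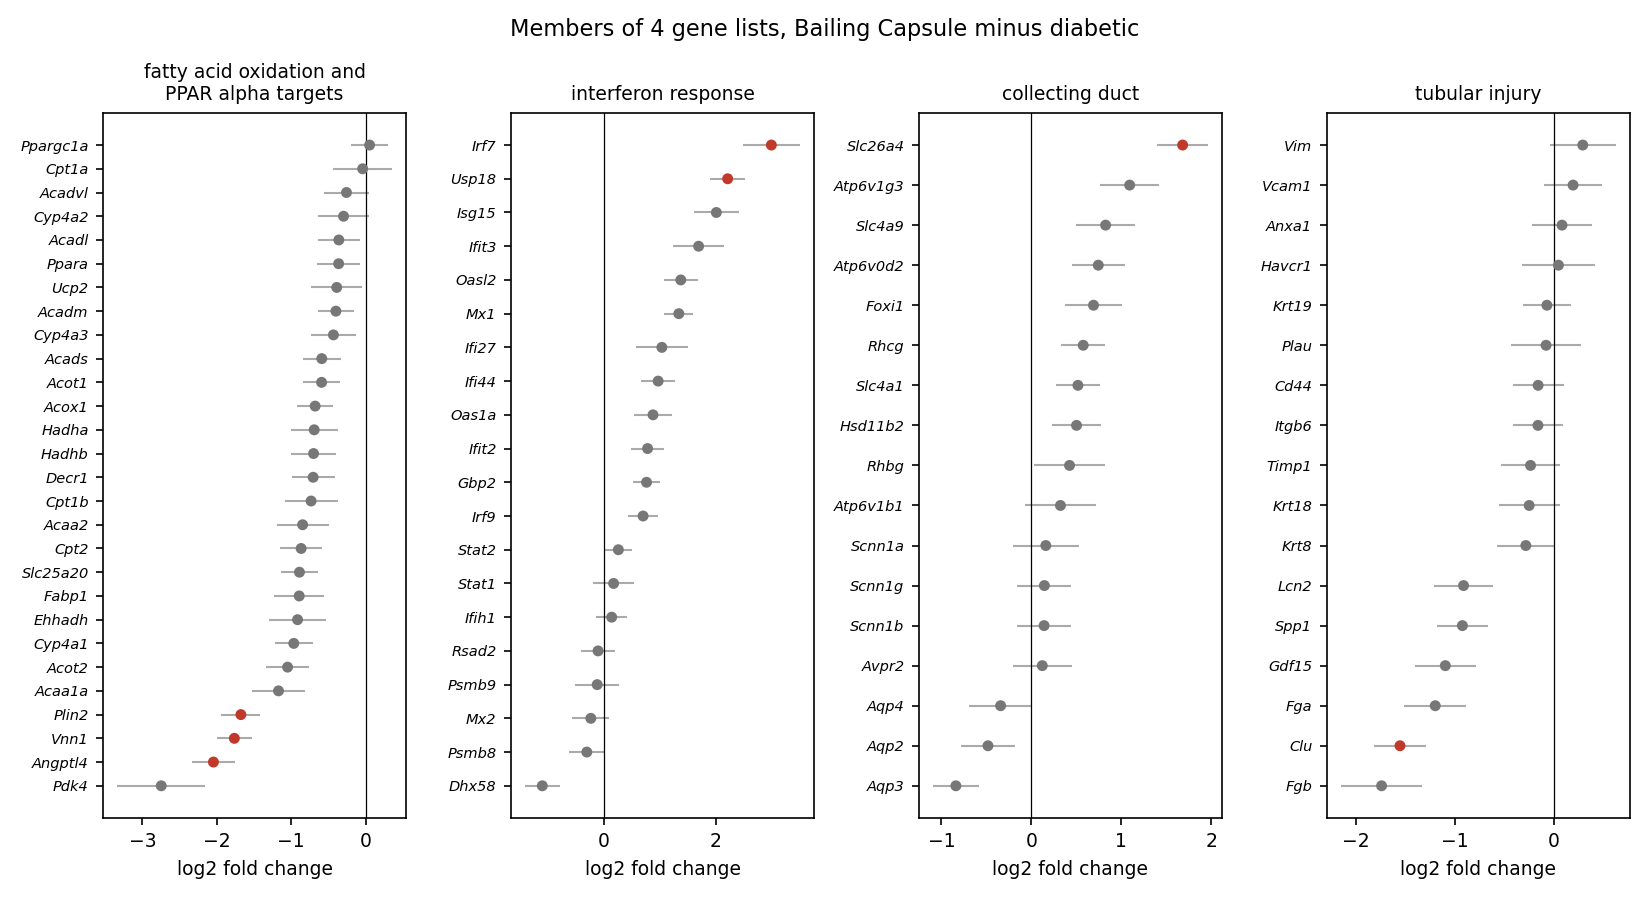
Log2 fold change (Bailing Capsule minus diabetic) of tested members of 4 lists; points are estimates, horizontal bars are standard errors of limma's fit on 3 arrays per group, and red marks an adjusted p under 0.05 over all genes. Angptl4, Vnn1 and Plin2 are the red points plotted for the fatty acid oxidation list, and Slc26a4 is the red point of the collecting duct list.

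The following genes, fixed in advance, showed no called difference. The podocyte slit gene Nphs1 had 0.46 and the glucose transporter gene Slc5a2 0.30. The matrix genes Col1a1 and Fn1 had -0.64 and -0.47, the chemokine gene Ccl2 -0.22 and Pck1, of gluconeogenesis, -1.09. Tgfb1 was below the filter and was not tested. The sign of Havcr1 and Ccl2 changed under at least 1 alternative.

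Cell type and pathway lists that did not pass camera at the preset correlation are given as median log2 fold change and adjusted p. Proximal tubule genes had -0.29 (0.433), loop of Henle and distal tubule genes 0.11 (0.189), podocyte genes -0.0050 (0.263), endothelial genes -0.16 (0.976) and mesangial, smooth muscle and fibroblast genes -0.07 (0.669). Urothelial genes had 0.25 (0.0691), adrenal genes -0.01 (0.669), macrophage and myeloid genes 0.19 (0.294) and lymphocyte genes 0.06 (0.433). With slide as a block, camera at the preset correlation also called podocyte genes (median 0.35) and urothelial genes (0.74), on a contrast that rests on 1 diabetic array. Extracellular matrix and fibrosis genes had -0.08 (0.9995), inflammatory signalling genes -0.08 (0.669), complement genes 0.08 (0.0765) and antigen presentation genes -0.20 (0.521).

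Oxidative phosphorylation genes had -0.26 (0.0691), with all 31 members negative and a median of 0.0016 with slide as a block. Part of that change is shared by all tested features, whose median was -0.0897, and 0.0887 with slide as a block. Glycolysis had -0.23 (0.558), gluconeogenesis and glucose handling -0.23 (0.308), fatty acid and triglyceride synthesis 0.0021 (0.0745) and cholesterol synthesis -0.14 (0.433). NRF2 and glutathione genes had -0.24 (0.0872), NADPH oxidase genes 0.05 (0.521), unfolded protein and amino acid stress genes -0.09 (0.653), heat shock genes -0.13 (0.771) and immediate early genes -0.05 (0.771). Cell cycle genes had -0.16 (0.123), autophagy and mTOR genes -0.19 (0.771), hypoxia and angiogenesis genes -0.04 (0.433), renin-angiotensin and mineralocorticoid genes -0.05 (0.771), vitamin D and phosphate genes -0.26 (0.469) and xenobiotic metabolism genes -0.26 (0.669). For the podocyte, adrenal, hypoxia, unfolded protein and immediate early lists the median was negative while camera, which compares a list with the other genes, gave the direction as higher. Of the sex chromosome list 1 member was tested, Rps4y2 at 0.06.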

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

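The fits within slide 1, with slide as a random block and with weights estimated gene by gene were chosen after the data were seen. All arrays were scanned on 1 day, so scan date as a block was not run. Of 29 called genes followed, 5 (Prima1, Gpr83, Atp12a, Mogat2 and Creb3l3) passed under every alternative followed by gene that gave a value, and none changed sign there. The test of each probe on its own was not among these alternatives. In it 8 features with several probes had a called probe, and 0 had every probe called. The further probe of Prima1 had -0.27 there (limma, adjusted p = 0.956 among single probes). With arrays left out or slide as a block the sign could not change, since the groups of a called feature did not overlap. The number of called features was 12 with normexp and quantile normalization, 6 with no filter, 37 at a minimum fold of 1.2 and 9 within slide 1, and 17 to 195 when 1 array was left out; apart from fewer arrays and more features tested, the cause was not tested. Array weights gave 135, and 4514 when estimated gene by gene. The default weights did not converge, and both estimates put most of the weight on 1 or 2 arrays while disagreeing on Bailing Capsule replicate 3 (0.0335 and 6.26), so neither count is relied on. With the replicate number as a replicate block 6 features were called. After the group means were removed, same-numbered samples correlated at -0.181, -0.14 and 0.0194, and no sample correlated best with its own number. This gave no sign of a pairing by number, but with 3 arrays per group it cannot exclude one.

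The number of called lists was 5 with no filter and with array weights, 0 with an estimated correlation, 2 with fry and 4 to 14 when 1 array was left out. With an estimated correlation every list call ended at an unchanged median: -0.70 for fatty acid oxidation, 0.78 for interferon, 0.43 for collecting duct, 0.69 for blood, -0.23 for tubular injury, -0.35 for p53, 0.17 for circadian clock and -0.66 for adipocyte. fry kept fatty acid oxidation and tubular injury. Over all alternatives the medians ran from -0.79 to -0.51 for fatty acid oxidation and from 0.37 to 1.09 for interferon. They ran from 0.29 to 0.63 for collecting duct and from 0.0493 to 0.97 for blood. Adipocyte genes did not pass with quantile (-0.65) or median (-0.63) scaling, deposited values (-0.62), no filter (-0.54) or weights (-0.47 and -0.41). Circadian genes did not pass with normexp (0.0871), quantile scaling (0.19), deposited values (0.24), no filter (0.15), the mean of probes (0.14), slide as a block or slide 1 alone (0.35) or gene-by-gene weights (0.0826). p53 genes did not pass with no filter (-0.39) or weights (-0.26), nor blood with weights (0.0493). Leaving out 1 array gave -1.09 to -0.37 for adipocyte, 0.0812 to 0.44 for circadian clock, -0.49 to -0.31 for p53 and -0.36 to -0.17 for tubular injury. The cause was not tested.

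Among uncalled genes, Havcr1 was -0.0209 in deposited values and -0.31 and -0.51 with weights, and within slide 1 or with slide as a block Ccl2 was 0.59. With the mean of a gene's probes RT1-Bb was -3.05, since its probes disagree. With 1 array left out, Havcr1 ran from -0.41 to 0.50 and Ccl2 from -0.63 to 0.19. Probes near background, such as those of Gpr83, Calca and Cga, limit the size of their differences.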

Other observations

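The tests of slide, proximal tubule cells, immune cells, collecting duct share and the level of liver markers were chosen after the results they bear on were seen; those of the change in liver markers and of other splits were set before their results were seen, although the liver test was prompted by the falls of Apoa4 and other genes abundant in liver, and the value of Cyp2c11 among its markers was already known. Lists that did not pass as a whole still held called genes. Scd2, a fatty acid desaturase, rose 4.27-fold (adjusted p = 0.0177; slide-blocked log2 value 2.35, adjusted p = 0.0573), while the fatty acid transporter gene Cd36 had -1.10 (adjusted p = 0.224). Cyp24a1 led the vitamin D list, where the calcium-binding protein gene S100g had -1.53 and the calcium sensor gene Casr 0.66, neither called. In the xenobiotic list Cyp1a1 had 2.99 (adjusted p = 0.0593) and Ugt2b15 -1.27. The class II gene RT1-Db1 fell 4.62-fold (slide-blocked log2 value -2.06, adjusted p = 0.0784), while a further probe of RT1-Db1 gave -0.51. The probe that stood for the class II gene RT1-Bb had 0.68 (adjusted p = 0.690), while another was well above background on all 3 diabetic arrays and on 0 Bailing Capsule arrays, and was at least 36.5-fold lower (adjusted p = 7.39e-06 among single probes). The labels give no strain, and why the probes disagree was not tested. Among myeloid genes the neutrophil genes S100a8 and S100a9 had -1.78 and -1.46 and the macrophage gene C1qc 0.98, none called. In glucose handling Slc2a2 had -0.94, Txnip -0.87 and Slc2a4 0.72. Apoa4, an apolipoprotein named after its value was seen, fell 4.87-fold (slide-blocked log2 value -1.75, adjusted p = 0.116). With slide as a block the calls of Scd2, RT1-Db1 and Apoa4 did not hold.

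The fatty acid oxidation and PPAR alpha list had a median of -0.70. Fewer proximal tubule cells would lower proximal tubule markers as much. Their median was -0.286 over 24 genes, which lay 0.418 above the list (SE 0.19, genes taken as independent). On that assumption this argues against that explanation as the whole cause. The proximal tubule genes had an estimated correlation of 0.30, however, and the SE holds no spread between samples, so this does not decide. Within slide 1 the difference was 0.739 (SE 0.23), on 1 diabetic array. Liver RNA in the diabetic libraries is a candidate explanation whose test, set beforehand as a median of liver markers below -0.70, came out as it predicts: of 15 liver markers, 1 of which is also in a fixed list, 10 were tested, 9 of them well above background on all 6 arrays, and their median was -0.983 (SE 0.41). Alb, F2 and Cyp2c11 were named after their values were seen. Alb was -2.69 in diabetic and -4.06 in Bailing Capsule kidneys, F2 had -1.99, and Cyp2c11, another liver gene, went the other way at 1.93. The median log2 signal of the 10 markers in diabetic kidneys, -2.11, was lower than the median log2 of the signal that list members lost, 1.34 (difference -3.45, SE 1.6). Signals of different probes share no scale, however, and 2 of the 10 markers lay above 1.34, so this does not decide, and liver RNA stays open. Within slide 1, where slide does not vary, the list median was -0.673. It rests on 1 diabetic array, whose own variation cannot be told from the group difference. A part played by slide in the value over all 6 arrays is therefore not excluded. The treatment itself stays open as an untested explanation.

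The interferon list had a median of 0.78. More immune cells would raise immune markers as much. The 26 macrophage, myeloid and lymphocyte markers had a median of 0.105, lying below the list by 0.672 (SE 0.32, genes taken as independent). On that assumption this argues against immune cell number as the whole cause over all 6 arrays. The interferon genes had an estimated correlation of 0.27, however, and the SE holds no spread between samples, so this does not decide. Within slide 1 the medians were closer, at 0.293 and 0.493 (difference -0.20, SE 0.22), and there they did not move apart by more than their spread. A slide difference may contribute to the median over all 6 arrays. The value of 0.493 comes from within 1 slide, where slide does not vary. It rests on 1 diabetic array, whose own variation cannot be told from the group difference. The treatment stays open, as does infection, which was not tested.

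The collecting duct list had a median of 0.43. A larger share of collecting duct in the tissue would raise both of its cell types. Yet 8 principal cell genes had a median of 0.132 and 9 intercalated cell genes 0.692 (difference -0.56, SE 0.26, genes taken as independent). On that assumption this argues against share alone over all 6 arrays. The list's genes had an estimated correlation of 0.23, however, and the SE holds no spread between samples, so this does not decide. Within slide 1 the medians were closer, at 0.438 and 0.688 (difference -0.25, SE 0.35), and there the cell types did not move apart by more than their spread. Within slide 1, where slide does not vary, the list median was 0.63. It rests on 1 diabetic array, whose own variation cannot be told from the group difference. A part played by slide over all 6 arrays is not excluded, and the treatment stays open.

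Among the 10 splits of the 6 arrays into 3 and 3, which are too few for a share under 0.05, the real split was the 1 that called as many as 57 features, and the highest other called 1. At an unadjusted p under 0.05 the real split gave 1350 features, and 1 other split, with diabetic 1 and Bailing Capsule 2 and 3 against the rest, gave 3870, the others 87 to 980. The first principal component (42.3% of the variance) parts the same arrays, which points to a structure across the treatment groups. On that component 3 of the 4 slide 1 arrays lay on 1 side and both slide 2 arrays on the other. Bailing Capsule 1, of slide 1, lay at 25.1, between the slide 2 arrays at 21.6 and 51.5. Slide alone therefore does not order the arrays, but it stays open as part of the source. Diabetic 1 and Bailing Capsule 2 and 3 also had the largest shares of probes well above background, at 69.28%, 73.46% and 70.7%. The other arrays had 64.55% to 67.25%, and the source of the structure was not tested. For gene lists 2 of the 10 splits called as many as 8, and the highest other called 9.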
